A study of Mus musculus with 9 samples.

How the data were processed

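RNA was measured in tumours grown from 3 variants of the mouse melanoma line B16-F10. The variants differ in L-histidine decarboxylase (HDC), the enzyme that makes histamine: HDC-A has a diminished, HDC-M an unmodified and HDC-S an enhanced capacity to produce it. There were 6 tumours per group. Per the labels, RNA of randomly chosen tumours of a group was pooled in equal amounts, 2 tumours per pool, which gave 3 pools per group and 9 arrays in all. Each pool was amplified and labelled with Cy5 and hybridised to an Agilent mouse array beside a Cy3-labelled reference, RNA of cultured HDC-M cells, which was the same on every array. There was no dye swap, so a dye effect is common to all groups and cancels in a difference between groups.

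The deposited scanner files hold intensity values, the mean brightness and the median local background of each spot in each dye, written per the file headers by Agilent Feature Extraction 8.5.1.1. They also hold, per the file headers, other columns, which mark spots as well above background, as saturated or as outliers and give the spot type. The authors' value table is in log10 units: it holds the log10 ratio of Cy5 over Cy3 and equals the deposited log10 ratio column of the scanner files at all 43790 spots on every array, within 1e-06. Its scale and direction were settled by that comparison, and no further centring was found. Each array had 41534 probe spots for 41174 distinct probes, 1942 positive and 314 negative control spots.

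The spots' mean signals were corrected with the normexp method (offset 50) and each array was normalised by loess with limma 3.58.1 in R 4.3.3. Control spots and outlier spots had weight 0 in the loess and were then left out. Spots of a probe were averaged. A probe was kept when its Cy5 signal was well above background on at least 3 of the 9 arrays, whatever their group, which kept 26870 probes and left out 14304. The same mark in the Cy3 channel was not used, since most negative controls carry it there. Arrays are limited in precision by their number, 3 per group.

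Probes were named by matching their accessions to a RefSeq gene table of the mouse. The accession itself named 22072 probes and another accession of the same probe named 135. Symbols in the probe descriptions named 605 probes directly and 490 through synonyms, 825 kept the name in the file, and 17047 had no symbol. The files do not name a genome build, so no coordinates are given. For gene lists, the probe with the highest mean intensity stood for its gene.

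The log2 ratios of tumour over reference were fitted with limma (lmFit, eBayes), with all 9 arrays in one model and no block. An F-test asked for any difference among the 3 groups, and 3 contrasts compared HDC-S with HDC-M, HDC-A with HDC-M and HDC-S with HDC-A. Adjusted p values are Benjamini-Hochberg over all probes kept, and the threshold was 0.05. The exact permutation tests of single genes are two-sided over the 10 splits of 3 against 3 arrays. With 27 gene lists, 81 tests were made with limma's camera at a preset inter-gene correlation of 0.01, adjusted together, and repeated with the correlation estimated per list. The lists were the histamine system, the IGF axis, elastic fibre and fibulins, pigmentation and melanocyte, macrophage, T and NK cell, B and plasma cell, mast cell and basophil, granulocyte, dendritic cell and MHC class II, MHC class I, interferon response, T helper cytokines, endothelial cell, angiogenic factors, fibroblast and collagen matrix, pericyte and smooth muscle, skeletal muscle, keratinocyte, adipocyte, erythroid, cell cycle, hypoxia and glycolysis, immediate early and heat shock, p53 and apoptosis, invasion and proteases, and polyamine metabolism. They hold 426 distinct genes that were measured.

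The groups, the comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule the text names the measured members of the histamine list, Fbln5 and Igf2r, and per comparison genes from the 10 highest and 10 lowest folds among probes with a symbol that pass and whose groups do not overlap. Fbln5 and Igf2r were singled out in the study's published account, so their values are not independent evidence. The rule also names the members with the smallest p of each list. For length, the text departs from it and gives these only for lists that pass, with passing members of the others. In simulated data made from 26870 probes, the fit of HDC-S against HDC-M recovered 68% of probes changed by 0.5 on the log2 scale and 93% of those changed by 1, and 3.59% of its calls were false. For HDC-A against HDC-M these shares were 64%, 89% and 6.71%, and for HDC-S against HDC-A 74%, 92% and 4.05%. The simulated noise was independent between probes and arrays, without the variation that genes of one pool share. These shares therefore check the fit and do not measure the accuracy of the real calls.

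The alternatives were no background correction, plain subtraction, the scanner software's ratios, the authors' value table, median centring in place of loess, loess followed by Aquantile or by scaling, the Cy5 channel alone after quantile normalisation, no filter and a stricter filter (20405 probes), outlier spots kept, array weights, a block for replicate number, a block for scan day, the compared groups alone, all probes of a gene averaged, an estimated correlation in camera, and leaving out each array in turn. The file headers give 2 scan days: replicates 1 and 2 of each group were scanned on the first day and replicate 3 on the second, each array on its own slide. The 6 arrays of the first day alone, and the probes without saturation alone, were alternatives chosen after seeing the data. The second day holds 1 array per group and allows no test. The groups share replicate numbers, and the pairing was checked by the correlation of same-numbered arrays' deviations from their group means. It was over 0.1 in all 3 pairs of HDC-A with HDC-S arrays (0.11, 0.55 and 0.13). HDC-A replicates 1 and 3 correlated more with HDC-S replicates 3 and 1 (0.22 and 0.20), and the pools hold randomly chosen tumours. A pairing by number is therefore not established, and the replicate block is given as an alternative to the unblocked fit. The correlation of same-numbered arrays was over 0.1 in 1 of 3 pairs of HDC-A with HDC-M arrays and in 0 of 3 of HDC-S with HDC-M arrays, which are taken as unpaired. Over all pairs its median was 0.03, against 0.02 for arrays of different number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.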

Results

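Gene expression was measured with 2-colour arrays in 9 pools of B16-F10 melanoma RNA, 3 from HDC-A tumours (diminished histamine production), 3 from HDC-M tumours (unmodified) and 3 from HDC-S tumours (enhanced). Values are log2 ratios of the tumour pool over a common reference of cultured HDC-M cells, so a positive mean is brighter in tumour than in culture. Each group came from 1 line variant, and line and histamine group cannot be separated. The Cy5 channel was well above background at 58.0% of the probe spots on the lowest array and 69.7% on the highest. Log2 ratios correlated across probes with r from 0.899 to 0.950 within groups and from 0.862 to 0.922 between groups.

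The first question was whether RNA of the modified gene itself, Hdc, followed the groups. Its only probe (A_51_P254656) was well above background in the Cy5 channel on all 9 arrays but dim. In the Cy3 channel, the reference, its signal was 0.97 to 1.08 times the median of the negative controls, so its ratios have a denominator at background level. The log2 ratio of Hdc was 0.24 ± 0.16 in HDC-A, 0.38 ± 0.28 in HDC-M and 0.46 ± 0.14 in HDC-S tumours (SD, n = 3). Hdc in HDC-S exceeded HDC-M by 0.08 (SE 0.14; exact permutation p = 0.8), and Hdc in HDC-A was below HDC-M by a log2 fold of -0.14 (exact permutation p = 0.6). Between HDC-S and HDC-A tumours Hdc differed by 0.22 (exact permutation p = 0.2), and the smallest p this design allows is 0.1. Both differences from HDC-M were smaller than the SD of either group compared. The difference between HDC-S and HDC-A exceeded the SD of each of these groups, and its 95% interval, -0.10 to 0.54, includes 0. The sign of the Hdc difference between HDC-S and HDC-M turned with the Cy5 channel alone (-0.046), with array weights (-0.0075), without HDC-M replicate 3 (-0.083) and on the first scan day alone (-0.157). In HDC-A against HDC-M the difference was larger with the scanner software's ratios and in the authors' value table (-0.46 in each) and on the first scan day alone (-0.39), and between HDC-S and HDC-A it reached 0.59, without passing in any of these. Of the other histamine genes, Hrh2, Hrh3, Slc18a2, Maob and Aldh7a1 were measured and none passed in any comparison. The lowest adjusted p among them in HDC-S against HDC-M was that of Hrh2 (-0.15, adjusted p = 0.261), whose Cy5 signal was well above background on 3 of the 9 arrays. The values of Hrh3 in HDC-A, HDC-M and HDC-S were 0.23, 0.04 and 0.16. The 2 probes of Slc18a2 differed in sign between HDC-S and HDC-M, and Aldh7a1 was well above background on 2 of 3 HDC-A arrays. Hrh1, Hrh4, Hnmt, Aoc1, Slc22a2 and Slc22a3 were too dim to be tested.

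**Figure D1:**
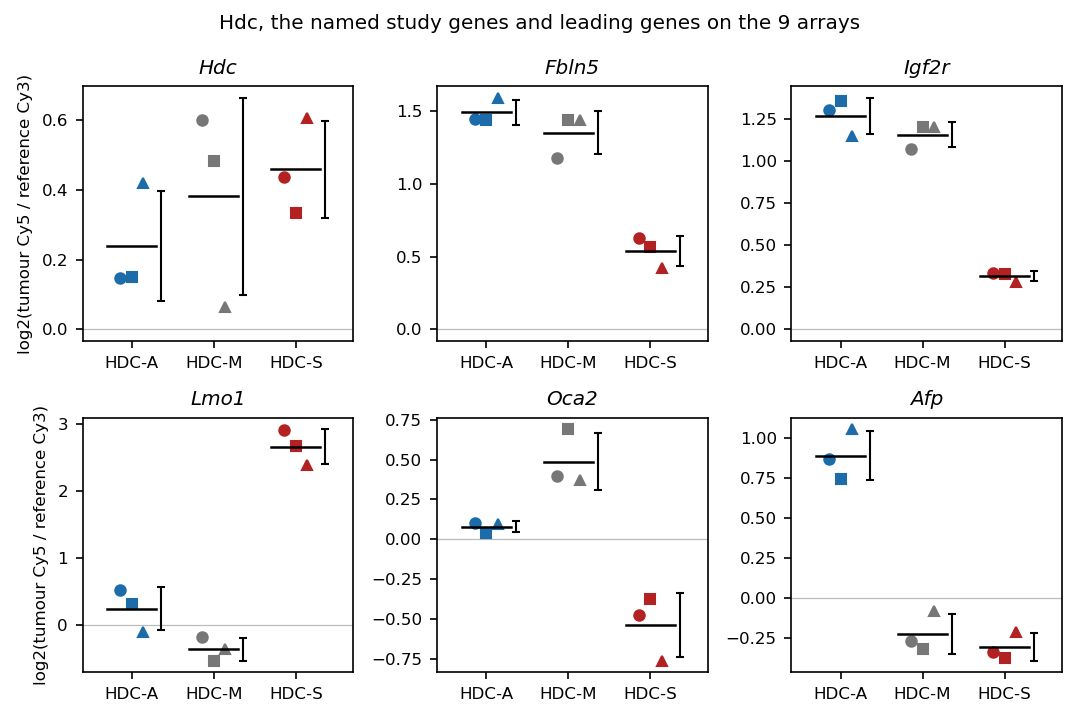
Log2 ratio of tumour (Cy5) over reference (Cy3) for Hdc, Fbln5, Igf2r, Lmo1, Oca2 and Afp on the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3, a line at the group mean and a bar of 1 SD (n = 3). Hdc overlaps between the groups, while Lmo1 averages 2.66 in HDC-S tumours against -0.37 in HDC-M tumours.

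Over all 3 groups, 1249 of 26870 probes differed by limma's F-test. HDC-M tumours had the middle mean at 742 of these probes (59.4%), HDC-S tumours at 299 and HDC-A tumours at 208. At 216 probes HDC-A tumours stood apart from both other groups, passing in the same direction against each, and at 126 probes HDC-S tumours did. HDC-M tumours stood apart at 32 probes, 16 lower and 16 higher than in both variants, among them Galnt6, Sytl2, Kit, Ahr and Gcnt1. Pfn2 and Upf3b passed in opposite directions, both lower in HDC-S and higher in HDC-A than in HDC-M tumours. Galnt6, Pfn2 and Upf3b were named after their values were seen. The F-test count was 5 under median centring, 102 with the scanner software's ratios, 105 in the authors' value table and 140 after scaling. It was 420 with the Cy5 channel alone, 729 with the replicate number as a block, 2052 with array weights and 6 on the first scan day alone. Leaving out 1 array at a time gave 341 to 1126 probes: 527, 815 and 434 without HDC-A replicates 1, 2 and 3, 454, 409 and 341 without HDC-S replicates 1, 2 and 3, and 471 and 392 without HDC-M replicates 1 and 2.

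The comparison of HDC-S with HDC-M tumours asks what raised histamine production goes with. Lmo1 rose most, by 3.03 on the log2 scale (SE 0.18, adjusted p = 0.000599), from -0.37 ± 0.17 in HDC-M to 2.66 ± 0.26 in HDC-S tumours (SD, n = 3), and it passed under every alternative tried. Smtnl2 rose by 1.93 (SE 0.25, adjusted p = 0.0215). Ahr rose by 1.22, Pdzrn3 by 1.12 and Scarf1 by 1.11. Amhr2 rose by 1.12 with 2 usable HDC-M arrays, and its sign turned in the authors' value table (-0.096). Batf, Acot1, Gcnt1 and Ddah1 rose by 0.77 to 0.88, and passed in 0, 2, 4 and 5 of 9 fits that left out an array. Of those 9 fits Pdzrn3 passed in 7, Smtnl2 in 5, and Ahr, Scarf1 and Amhr2 in 3 each. The 2 other probes of Gcnt1 (0.04 and 0.18) did not pass. Rhox5 fell most, by 2.46 (SE 0.36, adjusted p = 0.0279), and passed in 4 of those 9 fits. Igf2r fell by 0.84 (SE 0.07, adjusted p = 0.00436), from 1.16 ± 0.08 to 0.32 ± 0.03 (SD, n = 3), and passed in all 9. Fbln5 fell by 0.81 (SE 0.09, adjusted p = 0.0118), from 1.35 ± 0.15 to 0.54 ± 0.10 (SD, n = 3). Fbln5 passed in 6, and its dimmer second probe did not pass. Cngb1 fell by 1.03 and the pigmentation gene Oca2 by 1.02 (adjusted p = 0.0118), while Ppargc1a, Sytl2, Elovl7, Spsb4 and Itpr2 fell by 0.72 to 0.89. The second probe of Elovl7 (-0.29) did not pass. Itpr2 had 2 usable HDC-S arrays, and of its 2 other probes 1 also fell (-0.51, adjusted p = 0.0364) and the other had the opposite sign and did not pass (0.02, adjusted p = 0.948). Kit rose by 0.73 (adjusted p = 0.0192). Ahr (0.86), Pdzrn3 (0.62), Gcnt1 (0.83), Ddah1 (0.58) and Kit (0.44) also rose, and Sytl2 (-0.87) also fell, in HDC-A against HDC-M tumours. Each passed there too, so these changes were not particular to raised histamine production. Both comparisons share the HDC-M arrays. Oca2 passed in 6 of those 9 fits, Cngb1 in 5, Kit and Elovl7 in 4, Sytl2 and Itpr2 in 3, Spsb4 in 2 and Ppargc1a in 1. In all, 183 probes passed, 118 higher and 65 lower in HDC-S tumours, for 139 genes, and 12 differed over 2-fold. The share that was higher, 64.5%, was 48.6% of 37 probes after scaling, 50% of 10 with the Cy5 channel alone and 40% of 5 under median centring, and the scanner software's ratios and the authors' value table gave 7 probes each, no background correction 315 and array weights 635. The groups did not overlap at 22.3% of all probes, where chance gives 10% on average for probes without missing values. Probes of a pool vary together and the share was not computed for other splits, so this difference was not tested. Without HDC-M replicate 1 or 2 the count was 5 or 4, without HDC-S replicate 1, 2 or 3 it was 13, 7 or 8, without HDC-A replicate 1 or 3 it was 95 or 85, and without HDC-M replicate 3 it was 95. With scan day as a block, 85 probes passed, and on the first scan day alone 30, of which 7 were higher in HDC-S tumours. The replicate number as a block gave 70 probes, and the 2 groups compared alone gave 12.

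Among the gene lists, the keratinocyte genes shifted down in HDC-S against HDC-M tumours (camera adjusted p = 0.000138, and adjusted p = 0.995 with an estimated correlation). All 13 were lower, with a median log2 fold of -1.25, and the call held in all 9 fits that left out an array. Krt10 was lower by -2.35, Lor by -2.73 and Krt15 by -1.42. None of the 13 passed over all probes, and 5 fell when adjusted over the list alone. Hypoxia and glycolysis genes shifted up (adjusted p = 0.000192, and adjusted p = 0.995 with an estimated correlation), with 21 of 22 higher, Adm by 1.21 and Ndrg1 by 0.83. None passed over all probes, 4 rose when adjusted over the list alone, and the shift was lost under median centring (adjusted p = 0.138) and scaling (0.267). All 25 interferon response genes were higher (adjusted p = 0.00679, and adjusted p = 0.995 with an estimated correlation), Cxcl10 by 0.78 and Oas2 by 0.68. This shift was lost without HDC-M replicate 3 (adjusted p = 0.295), after scaling (0.172) and on the first scan day alone (0.395). All 21 macrophage genes were higher too (adjusted p = 0.0134, and adjusted p = 0.995 with an estimated correlation), Arg1 by 0.75 and Mrc1 by 0.61. The macrophage shift passed in 17 of 25 refits. Among the 25, Aquantile normalisation, no filter and array weights repeat the reported list test unchanged. It was lost without HDC-M replicate 3 (adjusted p = 0.775) or HDC-S replicate 2 (0.0714), on the first scan day alone (0.164), with no background correction (0.206), plain subtraction (0.161), the scanner software's ratios (0.680) or the authors' value table (0.698), and after scaling (0.902). HDC-M replicate 3 had the lowest mean of the 9 arrays for the macrophage (1.24, 1.75 or more on the others), T and NK cell (0.0030), mast cell and basophil (0.054), granulocyte (0.051), dendritic cell (0.61) and T helper cytokine (0.014) lists, and the highest share of spots well above background. Its low means were not confined to immune lists. It was also lowest for the endothelial (0.88), elastic fibre (0.415), angiogenic factor (0.447), invasion (0.478), polyamine (0.052) and histamine (0.011) lists. For the interferon response, MHC class I and B and plasma cell lists another array was lower. Cell cycle genes shifted down (adjusted p = 0.0284, and adjusted p = 0.995 with an estimated correlation), with 20 of 27 lower, Foxm1 by -0.42 and Ccna2 by -0.26. This shift was lost without HDC-S replicate 2 (adjusted p = 0.159), HDC-M replicate 1 (0.0517) or HDC-M replicate 3 (0.173). Pigmentation genes shifted down (adjusted p = 0.0317, and adjusted p = 0.995 with an estimated correlation), with 15 of 19 lower. Oca2 fell and Kit rose over all probes, and 4 fell and 2 rose when adjusted over the list alone. This shift was lost without HDC-S replicate 1 (adjusted p = 0.144), HDC-M replicate 2 (0.117) or HDC-M replicate 3 (0.0575), under median centring (0.0513) and with outlier spots kept (0.0529). Immediate early and heat shock genes shifted up (adjusted p = 0.0488, and adjusted p = 0.995 with an estimated correlation), with 16 of 19 higher, Hsph1 by 0.56 and Fos by 0.86. The immediate early and heat shock shift passed in 16 of 25 refits, with the same unchanged repeats among them. It was lost without HDC-S replicate 2 (adjusted p = 0.629), HDC-M replicate 2 (0.0536) or HDC-M replicate 3 (0.208), with no background correction (0.0810), plain subtraction (0.0849) or the scanner software's ratios (0.117), under median centring (0.0777), after scaling (0.132) and with the stricter filter (0.0590). With an estimated correlation no list passed in any comparison, and all 7 passed with scan day as a block.

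**Figure D2:**
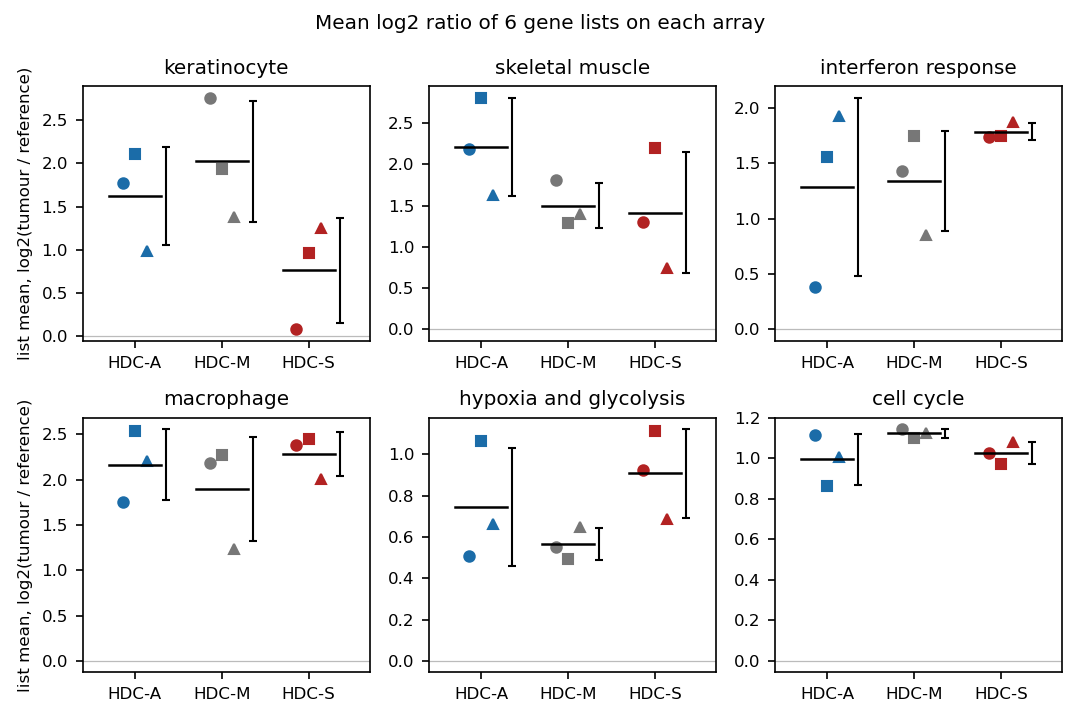
Mean log2 ratio of tumour over reference of the genes of 6 lists on each of the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3, a line at the group mean and a bar of 1 SD (n = 3). The interferon mean was 0.38 on HDC-A replicate 1 and 0.85 on HDC-M replicate 3, and at least 1.43 on the other arrays.

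The comparison of HDC-A with HDC-M tumours asks what lowered histamine production goes with. Hapln1 rose most, by 1.80 (SE 0.23, adjusted p = 0.0145), and passed in 6 of 9 fits that left out an array. Afp rose by 1.11 (SE 0.09, adjusted p = 0.00407), from -0.22 ± 0.12 to 0.89 ± 0.16 (SD, n = 3), and passed under every alternative that measured it, with folds from 0.87 to 2.49. Several genes of the p53 list rose. Cdkn1a rose by 0.98 (SE 0.10, adjusted p = 0.00659), from -0.56 ± 0.07 to 0.41 ± 0.22 (SD, n = 3), Trp53inp1 by 1.00 and Ccng1 by 0.81, while Bcl2 fell by 0.53. Fndc3c1 rose by 1.42, and Erbb3, Ctso, Sulf2 and Tspan2 rose by 1.00 to 1.11. The second probe of Erbb3 had the opposite sign, and those of Tspan2 (0.19, adjusted p = 0.227), Sulf2 (0.97, adjusted p = 0.0502), Trp53inp1 (0.49) and Bcl2 (-0.29) did not pass. Gxylt2 fell most, by 1.498 (SE 0.14, adjusted p = 0.00407), followed by Bdh1 with 1.24. Art5, Fez1, Sytl2, Gcat, Eogt, Gsta4 and 1700019D03Rik fell by 0.70 to 0.95. Of these, Sytl2 (-0.87) and Eogt (-0.71) also fell and passed in HDC-S against HDC-M tumours. App had a log2 fold of -0.73 with 1 usable HDC-M array, which is assumed to vary like the other groups, and passed in 1 of 8 fits that left out an array. Of the 9 such fits Cdkn1a, Gxylt2 and Fez1 passed in 9, 1700019D03Rik in 7, Bdh1, Art5 and Gcat in 6, Ctso in 5, Erbb3, Tspan2, Sytl2 and Gsta4 in 4, Trp53inp1, Ccng1, Bcl2, Sulf2 and Eogt in 3 and Fndc3c1 in 1. Fbln5 (0.14, adjusted p = 0.508) and Igf2r (0.11, adjusted p = 0.498) did not pass, and their sign turned under median centring, scaling and the Cy5 channel alone. In all, 387 probes passed, 207 higher and 180 lower in HDC-A tumours, for 288 genes, and 14 differed over 2-fold. The count was 18 with the scanner software's ratios (66.7% higher, against 53.5%), 16 in the authors' value table, 2 under median centring, 50 after scaling, 191 with the Cy5 channel alone and 644 with array weights. The groups did not overlap at 20.9% of all probes, where chance gives 10% on average, a difference likewise not tested. Without HDC-M replicate 1, 2 or 3 the count was 34, 21 or 150, without HDC-A replicate 1, 2 or 3 it was 140, 210 or 29, and without HDC-S replicate 1, 2 or 3 it was 218, 178 or 185. With scan day as a block, 189 probes passed, and on the first scan day alone 5. The replicate number as a block gave 193 probes, and the 2 groups compared alone gave 86.

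Skeletal muscle genes shifted up in HDC-A against HDC-M tumours (camera adjusted p = 0.00306, and adjusted p = 0.995 with an estimated correlation), with 17 of 19 higher, Myot by 1.06 and Myh2 by 1.43. None passed over all probes or when adjusted over the list alone, and the shift was lost without HDC-A replicate 2 (adjusted p = 0.0817) and after scaling (0.142). Cell cycle genes shifted down (adjusted p = 0.0060, and adjusted p = 0.995 with an estimated correlation), with 23 of 27 lower, Cdk1 by -0.40 and Mcm5 by -0.32. None passed over all probes, 4 fell when adjusted over the list alone, and the shift was lost without HDC-A replicate 2 (adjusted p = 0.249). Pigmentation genes shifted down (adjusted p = 0.0284, and adjusted p = 0.995 with an estimated correlation), with 13 of 19 lower. Syngr1 fell by 0.49 and Kit rose by 0.44 over all probes (passing in 1 and 0 of 9 fits that left out an array), and 8 fell and 1 rose when adjusted over the list alone. This shift was lost without HDC-A replicate 2 (adjusted p = 0.0589) or HDC-M replicate 2 (0.135), under median centring (0.0744), with the Cy5 channel alone (0.245) and with outlier spots kept (0.0655). The p53 list as a whole did not pass (adjusted p = 0.443), though 5 of its 17 genes rose and 1 fell when adjusted over the list alone. Emilin1, of the elastic fibre list, rose by 0.43, and passed in 0 of 9 fits that left out an array. All 3 passing lists also passed with scan day as a block and on the first scan day alone. That day keeps HDC-A replicate 2, without which each of these shifts was lost, so passing there is not independent support.

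**Figure D3:**
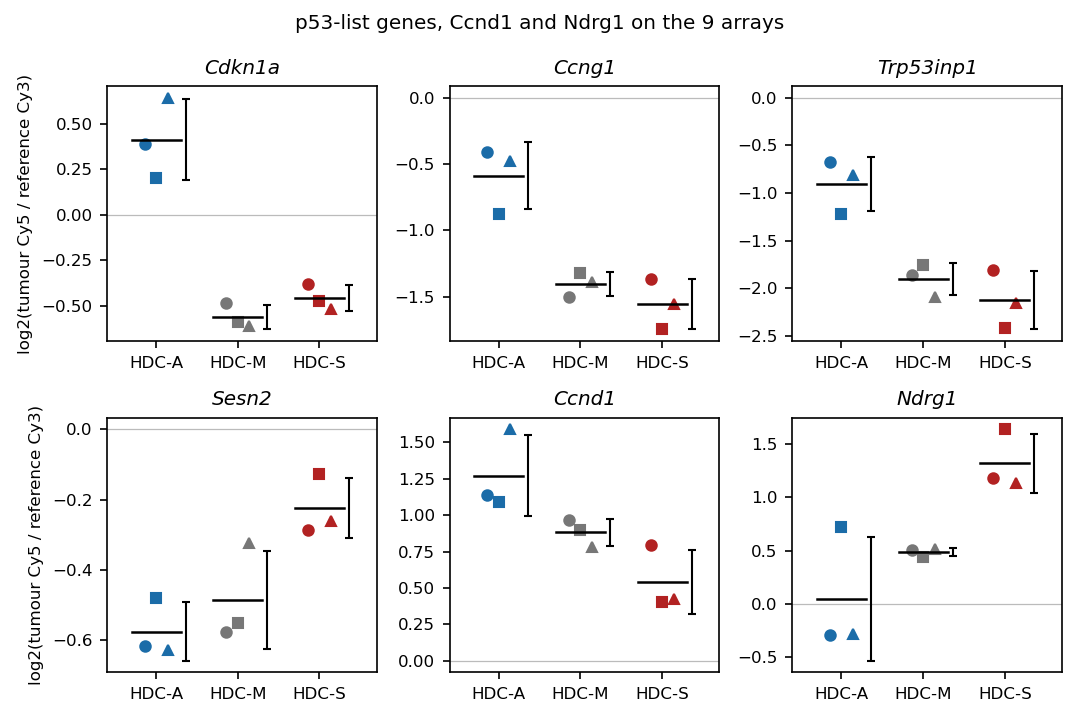
Log2 ratio of tumour (Cy5) over reference (Cy3) for the p53-list genes Cdkn1a, Ccng1, Trp53inp1 and Sesn2, and for Ccnd1 and Ndrg1, on the 9 arrays, with circles, squares and triangles for replicates 1, 2 and 3, a line at the group mean and a bar of 1 SD (n = 3). Cdkn1a averages 0.41 in HDC-A tumours, -0.56 in HDC-M tumours and -0.46 in HDC-S tumours.

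The comparison of HDC-S with HDC-A tumours sets the ends of the histamine series against each other. Lmo1 rose by 2.42 (SE 0.18, adjusted p = 0.00152) and passed under every alternative tried. Ndrg1 rose by 1.27, St3gal1 by 1.13 and Prph by 1.12, and Fkbp11, Gxylt2, Nnmt, Lgals3, Gcat and Gjc1 rose by 0.99 to 1.05. Fbln5 fell by 0.96 (SE 0.09, adjusted p = 0.00234) and Igf2r by 0.95 (SE 0.07, adjusted p = 0.00152), each lower on all 3 HDC-S arrays than on all 3 HDC-A arrays. Fndc3c1 fell most, by 1.40. Tspan2 fell by 1.29, Cngb1 by 1.23, Afp by 1.19 (adjusted p = 0.00181), Phyh by 1.17, Erbb3 by 1.05 and Pgap4 by 1.02. The second probe of Erbb3 again had the opposite sign, those of Tspan2 (-0.22, adjusted p = 0.119), Fbln5 (-0.08) and Fkbp11 (0.45) did not pass, and Afp was well above background on 1 of 3 HDC-S arrays, with folds of -0.91 to -2.76 under the alternatives. Zmat3 fell by 1.33 with 2 usable HDC-A arrays and Agt by 1.23 with 2 usable HDC-S arrays. Of the p53 list, Trp53inp1 fell by 1.22, Ccng1 by 0.97 and Cdkn1a by 0.87, while Sesn2 rose by 0.35. Of the cell cycle list, Ccnd1 fell by 0.73, Foxm1 by 0.46 and Ccnb1 by 0.43, while Mcm5 rose by 0.40 and Cdc6 by 0.37 (adjusted p = 0.0486), which passed in 5 of 26 alternatives. Of the pigmentation list, Oca2 fell by 0.62 and Tyr by 0.48, and Syngr1 rose by 0.45. Mcam fell by 0.72 (its second probe, -0.13, did not pass), Emilin1 fell by 0.39 and Mylk rose by 0.87. Of 9 fits that left out an array, Tyr passed in 8, Mylk in 7, Agt, Oca2, Foxm1, Ccnd1 and Mcam in 6, Ndrg1 in 4, Nnmt, Fndc3c1, Emilin1 and Syngr1 in 3, Prph and Mcm5 in 2, and Ccnb1, Sesn2 and Cdc6 in 1. With the replicate number as a block, Prph, Nnmt, Emilin1, Syngr1, Ccnb1, Sesn2 and Cdc6 did not pass (adjusted p from 0.0545 to 0.0641). In all, 1412 probes passed, 762 higher and 650 lower in HDC-S tumours, for 980 genes, and 26 differed over 2-fold. The count was 392 with the scanner software's ratios, 416 in the authors' value table, 4 under median centring, 158 after scaling and 532 with the Cy5 channel alone. The groups did not overlap at 24.4% of all probes, where chance gives 10% on average, a difference likewise not tested. Without HDC-A replicate 1 or 3 the count was 719 or 683, and without HDC-S replicate 1, 2 or 3 it was 648, 610 or 455. With scan day as a block, 1156 probes passed, and on the first scan day alone 9. The replicate number as a block gave 1126 probes, and the 2 groups compared alone gave 740.

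Skeletal muscle genes shifted down in HDC-S against HDC-A tumours (camera adjusted p = 0.0051, and adjusted p = 0.995 with an estimated correlation), with 18 of 19 lower, Mylpf by -1.36 and Myot by -0.77. Interferon response genes shifted up (adjusted p = 0.0166, and adjusted p = 0.995 with an estimated correlation), with 22 of 25 higher, Cxcl10 by 1.06 and Mx2 by 0.61. No gene of either list passed over all probes or when adjusted over the list alone. The interferon shift was lost without HDC-A replicate 1 (adjusted p = 0.918) and the muscle shift without HDC-A replicate 2 (0.0817). Both passed with scan day as a block and on the first scan day alone. The first day keeps HDC-A replicates 1 and 2, on which these shifts depend, so passing there is not independent support.

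The other lists passed in no comparison. For HDC-S against HDC-M tumours their adjusted p values were 0.703 for the histamine system, 0.70 for the IGF axis, 0.611 for elastic fibre and fibulins, 0.703 for T and NK cell, 0.615 for B and plasma cell, 0.869 for mast cell and basophil, 0.487 for granulocyte, 0.59 for dendritic cell and MHC class II, 0.703 for MHC class I and 0.99 for T helper cytokines. In the same comparison they were 0.869 for endothelial cell, 0.70 for angiogenic factors, 0.852 for fibroblast and collagen matrix, 0.852 for pericyte and smooth muscle, 0.705 for adipocyte, 0.59 for erythroid, 0.981 for p53 and apoptosis, 0.738 for invasion and proteases and 0.869 for polyamine metabolism. Against HDC-M the lowest adjusted p of these lists in HDC-A tumours was that of elastic fibre and fibulins (0.10). Between HDC-S and HDC-A tumours it was that of endothelial cell (0.141), which passed there with the replicate number as a block (adjusted p = 0.0306). With that block, elastic fibre and fibulins (camera adjusted p = 0.0235) and fibroblast and collagen matrix (0.0261) passed upward in HDC-A against HDC-M tumours. So did endothelial cell (0.0324) and macrophage (0.0329). Within the IGF axis Igf2r was the only gene that passed over all probes in HDC-S tumours, and 2 others rose against HDC-M tumours when adjusted over the list alone. The elastic fibre genes had Fbln5 as the only member that passed between HDC-S and HDC-M tumours. Keratinocyte genes did not pass between HDC-S and HDC-A tumours (adjusted p = 0.0867). Median and mean differed in sign for the granulocyte, p53, invasion, T helper cytokine and endothelial lists between HDC-S and HDC-M tumours. They also did for the dendritic cell list between HDC-A and HDC-M tumours, and for the IGF axis, B and plasma cell, angiogenic factor and T helper cytokine lists between HDC-S and HDC-A tumours. In HDC-A against HDC-M, camera pointed up for the granulocyte and the mast cell list and down for the T helper cytokine list, against the sign of both median and mean. Perp is a member of both the keratinocyte and the p53 list.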

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

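The fits to the first scan day alone and to probes without saturation were chosen only after the results were seen; the other alternatives were planned. Counts are given in the order F-test, HDC-S against HDC-M, HDC-A against HDC-M and HDC-S against HDC-A, and the cause of a change was not tested unless it is stated. The counts were within 1.5 times the reported 1249, 183, 387 and 1412 probes with plain background subtraction, without a filter, with the stricter filter, with outlier spots kept and without saturated probes. Aquantile normalisation leaves the log ratios untouched by construction and gave the same counts.

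No background correction gave 315 probes for HDC-S against HDC-M. The scanner software's ratios gave 102, 7, 18 and 392 probes, and those in the authors' value table gave 105, 7, 16 and 416 probes. Median centring without loess gave 5, 5, 2 and 4 probes and 11, 8 and 7 lists, in place of the reported 7, 3 and 2 lists. It moved the median log2 fold of all probes to -0.12 in HDC-S and -0.11 in HDC-A against HDC-M. Loess followed by scaling gave 140, 37, 50 and 158 probes and 4 lists for HDC-S against HDC-M. The Cy5 channel alone gave 420, 10, 191 and 532 probes. Array weights gave 2052, 635 and 644 probes in the first 3 tests. The share of passing probes that were higher in HDC-S than in HDC-M tumours was 64.5%, and 48.6% after scaling, 50% with the Cy5 channel alone and 40% after median centring. That share on the first scan day alone was 7 of 30 probes. In HDC-A against HDC-M it was 53.5%, and 66.7% with the scanner software's ratios.

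A replicate block gave 729, 70, 193 and 1126 probes and 7 lists for HDC-A against HDC-M. In HDC-S against HDC-A, where a pairing by number was not established, it gave 3 lists in place of 2, and 6 genes that the naming rule selects did not pass, while no other call among these genes changed there. The scan day block gave 85 and 189 probes for the comparisons with HDC-M. The first scan day alone, with fewer arrays, gave 6, 30, 5 and 9 probes, and 7 lists each for HDC-A against HDC-M and HDC-S against HDC-A. The compared groups alone, also with fewer arrays, gave 12, 86 and 740 probes in the pairwise tests. An estimated correlation gave 0, 0 and 0 lists by camera, where 7, 3 and 2 passed at the preset one.

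Leaving out 1 array at a time gave 341 to 1126, 4 to 189, 21 to 218 and 455 to 1389 probes, and 2 to 7, 0 to 10 and 2 to 6 lists. In HDC-S against HDC-M, 2 lists passed without HDC-M replicate 3 and 4 without HDC-S replicate 2. In HDC-A against HDC-M, 10, 0 and 8 passed without HDC-A replicates 1, 2 and 3, and in HDC-S against HDC-A, 6 passed without HDC-A replicate 3 and 5 without HDC-S replicate 3. None of the 12 list shifts turned its direction in any of 25 refits. Among these, Aquantile normalisation, no filter and array weights could not change the list tests. The blocks, and leaving out an array of the group not compared, leave the folds of genes without missing values unchanged. A turned direction was therefore hardly possible there. All 25 refits kept the preset correlation.

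Hdc passed under no alternative. Left out one at a time, its difference ranged from -0.083 (without HDC-M replicate 3) to 0.187 in HDC-S and from -0.303 to -0.033 in HDC-A against HDC-M, where it was -0.46 with the scanner software's ratios and in the authors' value table and -0.39 on the first scan day alone. It turned in HDC-S against HDC-M with the Cy5 channel alone (-0.046), array weights (-0.0075) and the first scan day alone (-0.157). With 1 probe for Hdc, no other probe of it could be tried.

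Of 81 passing results for genes that the naming rule selects, 80 kept their direction under every alternative. The exception was Amhr2 in HDC-S against HDC-M in the authors' value table (-0.096). Several alternatives cannot change a fold where no value is missing: Aquantile normalisation, the filters, the blocks, the probes without saturation and the compared groups alone. The same holds for leaving out an array of the group not compared. For these the direction was fixed in advance, and Aquantile normalisation leaves the p values unchanged too. Of 2099 alternative values for these results, 1380 still passed and 718 did not (290 of 728 where 1 array was left out), and 4 results passed under every alternative: Lmo1 in HDC-S against both groups, and Afp in HDC-A and in HDC-S against HDC-A. The other signs that turned belong to differences that did not pass. In HDC-A against HDC-M, Fbln5 and Igf2r turned under median centring (-0.31 and -0.29), scaling (-0.36 and -0.30) and the Cy5 channel alone (-0.095 and -0.023), which also turned Maob (-0.11). With 1 array left out, Maob ranged there from -0.010 (without HDC-M replicate 3) to 0.17, and in HDC-S against HDC-M from -0.13 to 0.051 (without HDC-M replicate 1). The Cy5 channel alone turned Hrh3 (-3.9e-05) and Aldh7a1 (0.023) in HDC-S against HDC-M, and Hrh2 (0.00042) in HDC-S against HDC-A. In HDC-S against HDC-A, no background correction turned Slc18a2 (-0.0078) and Aldh7a1 (-0.0053). With 1 array left out, Slc18a2 ranged there from -0.032 (without HDC-S replicate 2) to 0.056, with -0.018 without HDC-A replicate 2. Aldh7a1 ranged from -0.0073 (without HDC-S replicate 3) to 0.030, with -0.0047 without HDC-A replicate 1. The histamine genes were near the background, which limits their precision.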

Other observations

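The tests of graded order, of both explanations for Hdc and of saturation were chosen only after the results were seen, and the 3 added gene families below were chosen because their members stood out in the data.

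Host cell genes varied between pools within groups. The skeletal muscle mean ranged from 0.75 on HDC-S replicate 3 to 2.81 on HDC-A replicate 2, which also had the highest fibroblast and collagen matrix mean, 2.24. The keratinocyte mean ranged from 0.08 on HDC-S replicate 1 to 2.76 on HDC-M replicate 1. The MHC class I mean was 1.58 on HDC-A replicate 1 and 2.04 on HDC-M replicate 3, the arrays with the lowest interferon means, and 2.72 or more on the others. The polyamine metabolism mean was 0.06 ± 0.0015 in HDC-A, 0.12 ± 0.06 in HDC-M and 0.13 ± 0.03 in HDC-S tumours (SD, n = 3). That list did not pass by camera in HDC-A against HDC-M (adjusted p = 0.538) or HDC-S against HDC-A tumours (0.443). No member passed, and HDC-M replicate 3 (0.052) was below every HDC-A array.

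Chance alone is unlikely to give a count of 1249 probes that differ among the 3 groups, though single probes among them may be false calls. Of 100 splits of the 9 arrays, drawn from 280, 1 gave as many, the real one, and the highest other gave 119. The split by replicate number gave 0 probes by the F-test, and the scan day block 938. For the pairwise comparisons, 10 splits are too few for a share under 0.05. There 1 of 10 splits, the real one, gave as many probes each time, with 183 against 3 in the highest other for HDC-S against HDC-M, 387 against 0 for HDC-A against HDC-M, and 1412 against 1 for HDC-S against HDC-A, where the other 3 splits that part all same-numbered pairs gave 0. The Cy3 channel, which held the same reference RNA on every array, gave 0 probes by limma's F-test after quantile normalisation. At an unadjusted p under 0.05 it gave 1409, where the ratios gave 5623. This argues against slide and hybridisation differences only as far as they act on the Cy3 signal. Differences in amplification, in Cy5 labelling or in the balance of the dyes cannot appear in that channel, so they stay open. Different amounts of host cells may contribute and were not excluded. Probes at least 4-fold brighter in tumours than in the cultured reference had an odds ratio of 0.728 (95% interval 0.359 to 1.48) for being among the called probes, 8 of 1249 against 233 over all. Such probes vary more within groups (median residual SD 0.61 against 0.098), which lowers their chance of a call. Histamine production and any other difference between the line variants stay open as causes, since each group is 1 variant. Amounts of introduced DNA or selection of a clone were not tested.

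HDC-A and HDC-S tumours tended to differ from HDC-M tumours in the same direction, at 64.0% of probes. The shared HDC-M arrays could produce this alone. The covariance of the log2 folds was 0.0132, against a median of 0.00746 and a highest value of 0.0243 in 100 simulations of unchanged groups, and the correlation was 0.417 against a simulated median of 0.513. The overlap of 32 probes past both tests compares with 0.909 and 0.435 expected for higher and lower probes if the comparisons were independent. They share the HDC-M arrays and are not independent. The overlap that this sharing gives was not simulated, so a common response at these probes remains undecided. A graded response to histamine production could place HDC-M tumours in the middle, as at 59.4% of the F-test probes. Of the 100 splits drawn, 7, the real one among them, gave a share as high among as many top probes. The highest other was 80.1%, so that order remains undecided.

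The Hdc probe did not separate the groups, and in the reference channel its signal was at the level of the negative controls. Host mast cells and basophils may supply part of its signal: Hdc correlated with the mean of 7 mast cell and basophil genes with Pearson's r = 0.296 (permutation p = 0.44) and Spearman's rho = 0.333 (permutation p = 0.385) over the 9 arrays, the only such relation computed. Without the 2 arrays farthest from the median r was -0.639, so nothing is decided. Its signal may also be too close to background. After background subtraction it was 1.52 to 3.25 times the 90th percentile of the negative controls, where under 3 on every array would have favoured this explanation and over 10 spoken against it. Whether the probe can bind RNA of an introduced construct cannot be told from the files.

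Ribosomal protein genes may be higher in HDC-S tumours as a family. Against HDC-M tumours 61 of 68 were higher and 8 rose, and against HDC-A tumours 47 were higher and 16 rose. With the genes first seen left out, camera gave p = 0.05002 against HDC-M and p = 0.0841 against HDC-A with an estimated correlation (0.15 and 0.189 adjusted over the 9 family tests), so neither is decided. Of the 68 probes, 12 were saturated in both dyes on at least 1 array and carry little information there. Against HDC-M all 12 counted as higher, with folds of 0.135 to 0.346, so the count of 61 includes them. With unsaturated probes alone, 47 of 55 genes were higher in each comparison. On those genes camera did not pass in either comparison (limma, adjusted p = 0.201 for both, with an estimated correlation). The direction against HDC-M turned under median centring without loess, where the family's median was -0.36 and that of all probes -0.12. With the Cy5 channel alone it was nearly lost, with a median of 0.0056 and 40 of 68 higher. Against HDC-A it stayed positive under all 6 scaling alternatives, with a median of 0.026 to 0.153.

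Amino acid response genes, among them Asns, Chac1, Trib3 and Nars, may differ between HDC-S and HDC-A tumours. In all, 18 of 20 were higher in HDC-S and 7 rose, Asns by 0.85, and camera gave p = 0.0120 with an estimated correlation and the genes first seen left out. Adjusted over the 9 family tests this p was 0.103, which does not pass. Against HDC-M tumours 11 of 20 were higher in HDC-S (median 0.05) and 17 were lower in HDC-A (median -0.22), while after scaling both medians were positive (0.45 and 0.20). Under median centring both were negative (-0.26 and -0.62), where the medians of all probes were -0.12 and -0.11. Sterol synthesis genes, among them Sqle, Msmo1 and Fdft1, were higher at 17 of 18 members and 6 rose, Sqle by 0.72, but with an estimated correlation p was 0.262. Against HDC-M tumours 7 of 18 were higher in HDC-S (median -0.02) and 17 were lower in HDC-A (median -0.27). The direction of both families between HDC-S and HDC-A tumours held under no background correction, plain subtraction, the scanner software's ratios, median centring, scaling and the Cy5 channel alone.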
